A study of Plasmodium falciparum with 9 samples.

How the data were processed

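RNA of parasites exposed to anacardic acid and RNA of untreated parasites were hybridized together on oligonucleotide arrays of 16416 spots in 48 blocks, in which the 7250 parasite oligos were each printed in duplicate. Per the labels, the treated RNA carried Cy5 and the untreated RNA Cy3 on all 9 arrays, and equal amounts of labelled cDNA were mixed. No dye swap was included, so a dye effect specific to an oligo is part of every ratio against untreated RNA and cancels only between doses. The series' design text says that late trophozoites were taken for RNA. Groups and replicate numbers came from the sample titles.

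Per the file headers, images were scanned at 635 and 532 nm and quantified with GenePix Pro 6.0.1.27, with local background and no normalization. The intensity values deposited per spot are median foreground and median background of each channel, with the background SD. The files also hold the percent of saturated pixels of each spot, deposited by the authors, and the spot flags. A table of log2 values deposited by the authors holds 6361 unnamed rows, 5452 of them complete. Each of its columns has a median of 0. Matched to the scanner values, its values lay at a median distance of 0.138 from log2 of Cy5 over Cy3 and 0.37 with the sign turned, so scale, direction and centring were settled from the data. What else was done to make that table is not given in the sources used here. It served only as an alternative.

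Background was corrected by normexp with an offset of 50, and each array was normalized by global loess in limma 3.58.1 under R 4.3.3. Control spots had weight 0 in the loess curve, and spots with a negative flag were left out. Between 1070 and 3037 spots per array were flagged, and 5 to 15 were saturated and kept. Duplicate spots were averaged, and their SD was 0.0798 to 0.123 on the log2 scale. An oligo was kept if either channel exceeded background by 2 background SD on at least 6 of the 9 arrays, which left 6253 oligos, 6120 of them complete. The pla_ features passed the same filter, 39 of 41, and their adjusted p came from the same test with the oligos.

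One limma model with a mean per dose was fitted to the 9 arrays. Each dose mean was tested against 0, the doses against each other, and all doses by a moderated F-test, with Benjamini-Hochberg adjustment at 0.05, two-sided. If 1 untreated RNA served all arrays, which the labels do not say, this leaves out the spread of the untreated control itself. These designs, the alternatives, the rule for named oligos and 23 gene lists were fixed before the data were examined. The rule took, per dose, the 10 largest rises and 10 largest falls among called oligos that moved alike on 3 arrays, 5 for each contrast, up to 4 members of a list by smallest p, and 4 chromatin genes. The oligo identifiers matched 0 entries of the gene table, so 0 of the 23 lists and none of the chromatin genes could be tested, and identifiers were limited to 2 that rose and 2 that fell at 20 µM. The pla_ group was added after the data were seen and tested with camera (preset correlation 0.01, and estimated) and fry. Some of its members that the rule selects are not reported here.

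Replicate numbers were checked for pairing. Deviations from the dose means correlated at 0.45 to 0.92 between arrays of the same number. The numbers were therefore treated as pairing the arrays in an alternative fit, the replicate block, on the evidence of the data alone. The main model did not pair the arrays. These deviations largely set the arrays numbered 1 against the rest, and numbers 2 and 3 did not separate from each other. The first scan day held the arrays of 5 µM and replicate 1 of 10 µM, and the second the rest. Only 10 µM had arrays on both days, so a scan day block rests on its replicate 1 against its replicates 2 and 3. Such a block cannot tell scan day from the separation of the arrays numbered 1. Alternatives covered background, loess per block, median centring, scaling between arrays, the filter, flags, the deposited table, arrays fitted per dose, replicate and scan day blocks, and leaving out each array.

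The models were tested on simulated data of 6120 oligos. These data held deviations shared by arrays of one replicate number, but no spread of an untreated RNA common to all arrays. The false calls given here thus leave out any that such an RNA would cause. For 20 µM against untreated RNA, 72% of changes of 1 log2 unit and 97% of changes of 2 were recovered, and 38 of 207 calls were false. The model takes the 9 arrays as independent, whereas arrays of one replicate number deviated together. With the replicate block 95% and 100% were recovered, but 645 of 841 calls were false, since a block takes the mean of these 3 numbers as known. For 20 against 5 µM, 47% and 95% were recovered with 2 false of 144 calls, and with the block 87% and 99% with 10 false of 196.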

Results

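Expression was measured in *Plasmodium falciparum* 3D7, a laboratory strain of the malaria parasite grown in human erythrocytes, after exposure to anacardic acid, which the series names as an inhibitor of histone acetyltransferases. Synchronized ring-stage parasites 18 h old were exposed for 12 h to 5, 10 or 20 µM, and each dose had 3 arrays. Every one of the 9 arrays compared RNA of treated parasites, labelled with Cy5, with RNA of untreated parasites, labelled with Cy3. A log2 ratio above 0 is thus a higher level in treated RNA. Without a dye swap, a dye effect of an oligo cannot be told apart from treatment in any comparison with untreated RNA. The question the labels give is which transcripts changed level with treatment. The labels do not say whether replicates were separate cultures, nor whether the untreated RNA was 1 pool, so p-values measured only the spread between these arrays, which may be technical.

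The arrays carried 7250 parasite oligos, of which 6253 were detected on enough arrays to be tested. Median foreground intensity per array was at least 199 in Cy5 and 243 in Cy3, against median backgrounds of 37 to 47 and 37 to 42. The number of arrays limits the precision of every value. The oligos are listed by design identifiers that matched 0 entries of the gene table used here, so the changed oligos are described by number and size, with 4 identifiers. Features whose array names carry the prefix pla_ and a gene name could be named. These are ribosomal proteins, tRNAs, open reading frames, the elongation factor gene tufA, the Clp gene and LSU, names of the kind used for the plastid (apicoplast) genome of this parasite. The array design files them among its negative controls, and they were picked as a group after the data had been seen.

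At 5 µM, 1045 of the 6253 oligos differed between treated and untreated RNA (limma, Benjamini-Hochberg adjusted p under 0.05). Of these, 438 were higher and 607 lower in treated RNA. Among the 1045, 138 differed at least 2-fold. The median log2 ratio was 0.59 for those higher and -0.68 for those lower. The 10 largest rises lay between 1.11 and 1.86 and the 10 largest falls between -1.66 and -3.09 on the log2 scale. With median centring in place of loess, 29.7% of the calls were higher, against 41.9% here. The count was 627, 416 and 316 without replicates 1, 2 and 3 of this dose, and 687 without replicate 2 of 20 µM. It was 3005 with replicate number as a block, 612 with scan day as a block and 126 from the 3 arrays of this dose alone.

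Of the 39 pla_ features tested, 21 fell at 5 µM and 0 rose, and their median log2 ratio was -0.71, a ratio of 0.61. The 3 arrays had medians of -1.10, -0.41 and -0.47. Those that fell included 12 of 16 ribosomal proteins, 6 of 15 tRNAs and 2 of 5 open reading frames, and differences between these kinds were not tested. The feature rpl4, named for a protein of the large ribosomal subunit, fell by 1.51 on the log2 scale (SE 0.20, n = 3, limma adjusted p = 0.00273 by Benjamini-Hochberg). Of features named for proteins of the small subunit, rps3 fell by 0.99 and rps12 fell to 0.442 of the untreated level, and each of these 3 features was below 0 on 3 of 3 arrays. Against all other oligos the group was lower at a preset correlation of 0.01 (camera in limma, p = 1.03e-11). The correlation estimated from these features was 0.558, and with it camera gave p = 0.139. The p-values at the preset correlation, here and at the other doses, take the features as nearly independent, which this estimate contradicts. The number that fell was 11 without replicate 1 or without replicate 3 of this dose, 5 with scan day as a block and 1 from the arrays of this dose alone, where rpl4, rps3 and rps12 no longer passed. In these last 2 fits the median log2 ratio was -0.715 and -0.713.

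At 10 µM, 680 oligos changed, 299 higher and 381 lower (limma, Benjamini-Hochberg), and 99 of them changed at least 2-fold. The median log2 ratio was 0.61 for those higher and -0.65 for those lower. The 10 largest rises lay between 1.10 and 1.39, and the 10 largest falls between -1.59 and -3.23. The count was 409, 162 and 164 without replicates 1, 2 and 3 of this dose, and 408 without replicate 2 of 20 µM. It was 2510 with the replicate block, 1254 higher and 1256 lower, and 22 from the 3 arrays of this dose alone, 0 of them higher. Without replicates 1, 2 and 3 of this dose, 179, 42 and 34 were higher and 230, 120 and 130 lower.

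The pla_ features had a median log2 ratio of -0.50 at 10 µM, a ratio of 0.707, with array medians of -0.49, -0.51 and -0.41. Of the 39, 11 fell and 0 rose: 4 of 16 ribosomal proteins, 6 of 15 tRNAs and 1 of 5 open reading frames. The feature rpl4 fell by 1.20 (SE 0.20, n = 3, limma adjusted p = 0.00841, Benjamini-Hochberg). The histidine tRNA feature fell by 0.86 and the aspartate tRNA feature fell by 0.64. Not all members lay below 0. The feature ORF79, named after its value was seen, had a log2 ratio of 0.62 (limma adjusted p = 0.117). With the replicate block 22 features fell and 2 rose, among them ORF79 (limma adjusted p = 0.0411). The shift of the group had p = 3.73e-08 by camera with a preset correlation and p = 0.218 with an estimated correlation. The number that fell was 6, 1 and 2 without replicates 1, 2 and 3 of this dose, 18 without replicate 1 of 5 µM and 1 from the arrays of this dose alone, where rpl4 and both tRNAs no longer passed at unchanged log2 ratios. Without replicate 2 of this dose the calls of both tRNAs and of rpl4 ended, and without replicate 3 those of rpl4 and the aspartate tRNA (limma adjusted p between 0.0573 and 0.0692).

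At 20 µM, 503 oligos changed, 206 higher and 297 lower (limma, Benjamini-Hochberg), 65 of them at least 2-fold. The median log2 ratio was 0.60 for those higher and -0.72 for those lower. The oligos with the 2 largest rises and falls were followed across doses. Oligo L2_238 had log2 ratios of 1.40, 1.09 and 1.25 at 5, 10 and 20 µM (SE 0.12, n = 3, limma adjusted p = 0.00238 at 20 µM). Oligo E8314_2 had 1.38, 1.37 and 1.37 (SE 0.31, limma adjusted p = 0.032 at 20 µM). Oligo F7828_1 had -3.09, -3.23 and -2.63 (SE 0.48, limma adjusted p = 0.016 at 20 µM), which is 0.162 of the untreated level at 20 µM. Its value at 20 µM was -3.35 without replicate 3 of that dose. Oligo J116_3 had -1.63, -1.21 and -2.12 (SE 0.28, limma adjusted p = 0.00599 at 20 µM). Each of the 4 moved the same way on 3 of 3 arrays of each dose. The call of L2_238 at 20 µM held with each array left out. That of E8314_2 ended without replicate 1, 2 or 3 of 20 µM or replicate 2 or 3 of 5 µM, that of F7828_1 without replicate 1 or 2 of 20 µM, and that of J116_3 without replicate 2 of 20 µM. With scan day as a block the calls of E8314_2, F7828_1 and J116_3 ended, at log2 ratios of 1.89, -2.47 and -1.83. That block rests on the 10 µM arrays alone, replicate 1 against replicates 2 and 3. It thus cannot tell scan day from replicate number. The calls of all 4 oligos ended when the arrays of 20 µM were fitted alone, at unchanged log2 ratios. The count at 20 µM was 314 and 27 without replicates 1 and 2 of this dose, 13 higher and 89 lower without replicate 3, 329 without replicate 3 of 5 µM and 274 without replicate 2 of 10 µM. It was 841 after scaling between arrays and 0 from the arrays of this dose alone. The replicate block gave 2294, and there more oligos were higher, 1178, than lower, 1116. In simulated data 645 of 841 calls of that fit were false. Scan day as a block gave 55, 10 higher and 45 lower, and median centring in place of loess gave 132 higher and 291 lower.

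At 20 µM the pla_ features had a median log2 ratio of -0.55, a ratio of 0.682, and array medians of -0.51, -0.50 and -0.81. Of the 39, 13 fell and 0 rose, among them 6 of 16 ribosomal proteins and 6 of 15 tRNAs. The feature rps3 fell by 1.09 (SE 0.14, n = 3, limma adjusted p = 0.0054, Benjamini-Hochberg), rpl4 fell by 1.31 and the phenylalanine tRNA fell by 0.89. The shift of the group had p = 9.54e-14 by camera with a preset correlation and p = 0.111 with an estimated correlation. Adjusted over the 3 doses, these camera tests gave adjusted p = 0.209, 0.218 and 0.209 with an estimated correlation (limma). The group was also tested against a log2 ratio of 0, without other oligos as the comparison. This gave adjusted p = 0.00998, 0.0185 and 0.00998 at 5, 10 and 20 µM (fry in limma, Benjamini-Hochberg over the 3 doses). The fry test takes the arrays as independent, although arrays of one replicate number deviated together. A dye effect shared by the features would also give a small p in it. The number that fell at 20 µM was 7, 1 and 2 without replicates 1, 2 and 3 of this dose, 24 without replicate 1 of 5 µM and 7 without replicate 2 of 10 µM. It was 27 with the replicate block, 24 after scaling between arrays, 1 with scan day as a block and 0 from the arrays of this dose alone, where the median log2 ratio was -0.556 and -0.552. Scan day as a block ended the calls of rps3, rpl4 and the phenylalanine tRNA, at log2 ratios of -0.90, -1.37 and -0.87. Leaving out replicate 2 of this dose or replicate 3 ended those of rpl4 and the phenylalanine tRNA.

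**Figure D1:**
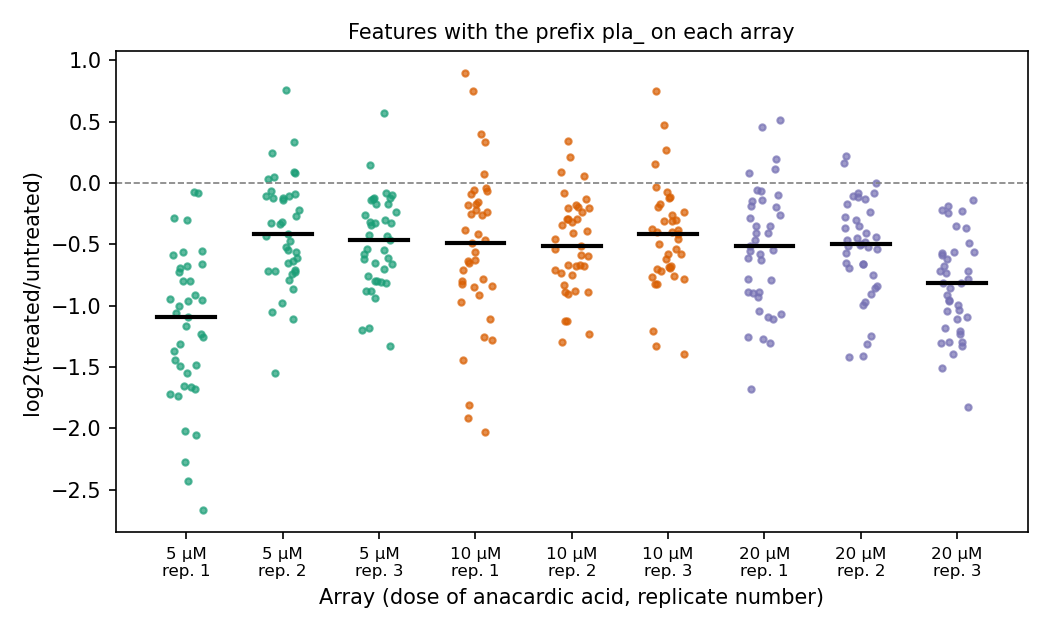
Log2 ratio of treated to untreated RNA (vertical axis) for the 39 features with the prefix pla_ on each of the 9 arrays (horizontal axis, dose and replicate number). Each point is a feature and each black bar the median of an array. The medians lie between -1.10 and -0.41, all below 0.

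The doses were then compared with each other, to ask whether the response changed with dose. For 10 against 5 µM, 20 against 10 µM and 20 against 5 µM, 0 oligos differed (limma, Benjamini-Hochberg), and 35, 27 and 56 had an unadjusted p under 0.05, where chance would give 313. A test for any difference among the 3 doses also found 0 oligos, with 32 at an unadjusted p under 0.05. With replicate number as a block the counts were again 0, with 312, 149 and 419 oligos at an unadjusted p under 0.05. Without the block, replicate number, which held 75.1% of the variance, counts as spread. The numbers below chance in that fit are therefore no evidence that the doses were alike. Within a scan day 10 against 5 µM and 20 against 10 µM also gave 0 oligos, but the first day held 1 array of 10 µM and the second 2, which is too few to say that the doses did not differ. The 95% interval of the difference lay within 1 log2 unit of 0 for 83.7%, 86.2% and 83.6% of the oligos in the 3 comparisons. With the block these shares were 98.8%, 99% and 98.5%. For the pla_ features 0 differed between doses, and their median differences were 0.19, -0.11 and 0.08. As a group they gave p = 2.41e-07, 8.77e-06 and 0.209 for these contrasts by camera with a preset correlation. With the replicate block these were p = 0.000145, 0.000252 and 0.407 at the preset correlation, and p = 0.416, 0.432 and 0.853 with an estimated correlation.

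Calls against untreated RNA overlapped between doses. At 5 and 10 µM 238 oligos were higher and 342 lower at both doses, where independent lists would share 20.9 and 37. At 10 and 20 µM these numbers were 169 and 252, against 9.9 and 18.1, and at 5 and 20 µM 184 and 275, against 14.4 and 28.8. At all 3 doses 408 oligos were called in the same direction, 160 of them higher, and 0 were called in opposite directions. The correlation of mean log2 ratios across oligos, which are not independent replicates, was 0.91, 0.92 and 0.90 for these pairs of doses. Simulations were made without a treatment effect. In them all arrays shared 1 untreated RNA, and arrays of one replicate number deviated together across doses. They gave a median correlation of 0.918. Simulated overlaps, both directions together, had medians of 293, 290 and 294 oligos and were at most 333, 318 and 335. The observed overlaps, higher and lower added, lay above these. But the observed lists at 5, 10 and 20 µM were also longer, 1045, 680 and 503 oligos against simulated medians of 382, 376 and 384. Longer lists share more oligos, so this comparison cannot decide on its own. The observed covariances were 0.145, 0.123 and 0.135, and the simulated ones 0.153, 0.154 and 0.153. A shared untreated RNA together with replicate deviations shared by the doses thus gave correlations and covariances about as large as those observed. Neither is therefore evidence of a treatment effect. Independent lists are a weak comparison too, since the doses shared the dye orientation and 1 estimate of the spread. Part of the overlap may come from shared untreated RNA, from replicate deviations shared by the doses or from dye effects of the oligos.

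The arrays numbered 1 stood apart from the others whatever their dose. Across oligos the log2 ratios of the 3 arrays numbered 1 correlated with each other at 0.83 to 0.92, although their doses differed. Those arrays correlated with arrays numbered 2 or 3 at 0.00 to 0.45, and at 0.10 to 0.33 within a dose. Arrays numbered 2 and 3 correlated at 0.74 to 0.90 and did not separate by number. Replicate 2 of 5 µM, for example, correlated at 0.74 with replicate 2 and at 0.90 with replicate 3 of 10 µM. Replicate number accounted for 75.1% of the variance of the log2 ratios around their means and dose for 8.74%. Levels of 2889 oligos differed among the replicate numbers (limma F-test, Benjamini-Hochberg). Without the 3 arrays numbered 1, a choice made after seeing the data, the counts at 5, 10 and 20 µM were 2982, 2545 and 2449, with 1241 higher and 1208 lower at 20 µM. The pla_ features that fell at 10 and 20 µM then numbered 23 and 30. This choice removed the arrays that stood apart, and with them much of the spread. The fit was not tested on simulated data, so these counts do not give the number of changed oligos.

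**Figure D2:**
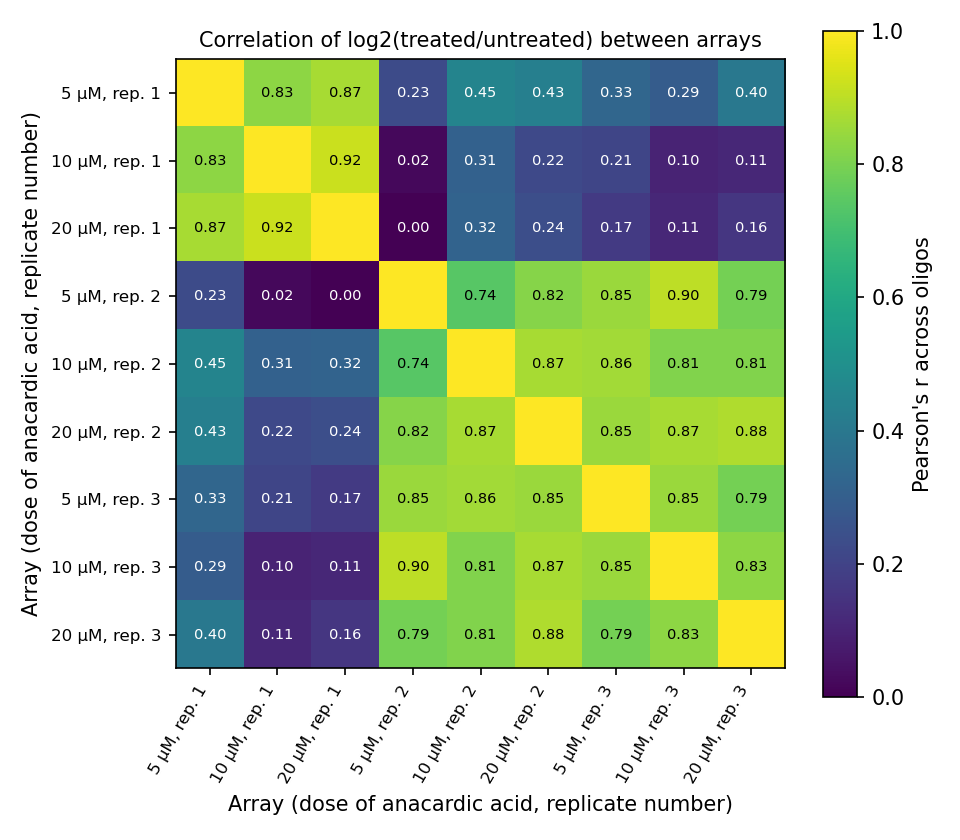
Pearson correlation, across oligos, of the log2 ratios of treated to untreated RNA for each pair of the 9 arrays, with both axes listing arrays by replicate number and then dose, and colour giving the correlation. The arrays numbered 1 correlate at 0.83 to 0.92 with each other and at 0.00 to 0.45 with the others.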

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

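Of the tests below, those of the untreated channel, scan day, a shared untreated RNA and a dye effect were chosen after the results they bear on had been seen.

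Signal appeared in features that the array design files as negative controls. In both channels 35 of the 41 pla_ features lay above the 95th percentile of empty spots (56 in Cy5 and 6 in Cy3, net intensity). So did 2 of the 20 yeast intergenic features, the brighter of which had a net intensity of 24853 in Cy5 and 21527 in Cy3, while 0 of 18 spike-in features and 0 of 6 transgene markers did.

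The pla_ features had lower levels in treated RNA at each dose, with a highest array median of -0.41. None of 10000 lists of parasite oligos matched on brightness had a median as low at 20 µM. The share was 1e-04 with the group itself counted, the smallest that so many lists can give. But the loess curve was fitted to parasite oligos alone, so lists of them centre near 0 at any brightness. The lists also leave out the correlation among the pla_ features, so this test cannot decide on brightness. The pla_ features lay below their 10 nearest parasite spots by a mean of -0.63 (SE 0.06), which argues against position on the slide. This SE takes the 39 features as independent, although their estimated correlation was 0.558, so it is too small. A dye effect cannot be told apart from treatment, since every array had the same dye orientation and 9 of 9 medians were below 0. A lower level of plastid transcripts may be the cause, as a hypothesis that a dye swap would test.

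The arrays numbered 1 stood apart from those numbered 2 and 3. The untreated channel held 3.75% of the variance of that difference, which argues against a different untreated RNA as the main source. Arrays numbered 1 and scanned on different days correlated at 0.87 or more, above 0.33, the highest value for an array numbered 1 with one numbered 2 or 3 of its own day, which argues against scan day. Among the 2085 brightest oligos the gap in median correlation was 0.57, against 0.64 over all, which argues against weak signal. A difference in the treated parasites, such as their age, or in the Cy5 labelling may be the cause, and neither was tested.

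Calls against untreated RNA may owe part of their number to a single untreated RNA used on all arrays. Simulations with no treatment effect and such an RNA called a median of 384 oligos and at most 420 at 20 µM, against 503 observed. At 5 and 10 µM they called at most 429 and 423, against 1045 and 680. They assume that an untreated culture varies as the replicate numbers do, and they also let arrays of one number deviate together. Untreated channels of arrays numbered 1 and of the others correlated at a median of 0.98, against 0.979 within these 2 sets. For the treated channel these values were 0.946 and 0.978. A single untreated RNA would leave such an untreated channel without replicate structure, but so would untreated cultures that were alike. The explanation stays open and cannot be told apart from treatment in this design. Nor can a dye effect of the oligos, since no dye swap was made.

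Other arrangements of the arrays were also counted. For any difference among doses, 100 of 100 groupings of the 9 arrays called as many oligos as the real one, but the real count was 0, so this says nothing about chance. The highest other count was 3471, from a grouping that kept the arrays numbered 1 together, and it points to a structure that sets these arrays against the rest. Grouping by replicate number called 2889. For each contrast of doses the real count was also 0, which 10 of 10 splits reach whatever the data, and the highest other was 0, also among the 4 splits that part all 3 pairs. Exchanging treated and untreated on the 3 arrays of a dose allows 4 ways, and 1 of 4, the real one, reached 1045, 680 or 503, with 0 the highest other. Neither 10 splits nor 4 ways are enough for a share under 0.05.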

How the results depend on the processing

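Leaving out the arrays numbered 1, the estimated correlation, the tests within a scan day and the pla_ group were chosen after seeing the data; the planned settings were then applied to that group. The 4 named oligos at 20 µM, the pla_ features named as having fallen and the pla_ shift kept their direction under the alternatives run on them, which leave out the deposited table. The balance of calls at 20 µM turned, from 206 higher and 297 lower to 1178 and 1116 with the replicate block and 1241 and 1208 without the arrays numbered 1. In simulated data 645 of 841 calls of the block at 20 µM were false, and the fit without the arrays numbered 1 was not tested there. Background, loess per block, median centring, no filter and ignored flags kept every total of calls within 1.5 times, but with median centring 132 rather than 206 were higher at 20 µM. Pairing by replicate number, the replicate block, gave 3005, 2510 and 2294 calls at 5, 10 and 20 µM against 1045, 680 and 503, and 22 and 27 pla_ features that fell at 10 and 20 µM against 11 and 13. At 10 µM 2 pla_ features rose with the block, against 0. It moved no other total past that bound. Scaling between arrays gave 841 calls and 24 pla_ features at 20 µM. Scan day as a block gave 612 and 55 calls at 5 and 20 µM, and 5 and 1 pla_ features. Since it rests on replicate 1 against replicates 2 and 3 of 10 µM, these changes cannot be assigned to scan day. The arrays of each dose alone gave 126, 22 and 0 calls and 1, 1 and 0 pla_ features, with fewer arrays behind each estimate of the spread. Without the 3 arrays numbered 1 there were 2982, 2545 and 2449 calls, and 23 and 30 pla_ features at 10 and 20 µM. Leaving these arrays out removed much of the spread by choice, so the counts do not give the number of changed oligos. The deposited table, whose rows are unnamed, gave 1 oligo for 20 against 10 µM and 1 for 20 against 5 µM, against 0. With an estimated correlation the pla_ shifts of -0.713, -0.501 and -0.552 had p = 0.139, 0.218 and 0.111 (camera). Apart from the arrays of each dose alone, the cause was not tested. Leaving out each array gave 316 to 1232, 162 to 826 and 27 to 637 calls against untreated RNA, and 0 to 0 between doses and among them. The pla_ shift then lay between -0.852 and -0.485, -0.522 and -0.448, and -0.661 and -0.482, and 11 to 22, 1 to 18 and 1 to 24 of its features fell. Tests of gene lists and the mean of several oligos of a gene were not run, since no oligo matched a gene. Median Cy5 foreground of 199 over a background of 37 was the weakest signal of an array.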

Other observations

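Few other features carried a gene description, and 3 of them were detected on enough arrays to be tested. They were picked after the data had been seen. The feature tRNA-1, listed as a tRNA, rose by 0.67 on the log2 scale at 5 µM (SE 0.08, n = 3, limma adjusted p = 0.00217, Benjamini-Hochberg) and by 0.34 at 10 µM (limma adjusted p = 0.0328). At 20 µM its log2 ratio was 0.23 (limma adjusted p = 0.123). The feature tRNA-2 rose by 0.62 at 10 µM (SE 0.12, limma adjusted p = 0.0189), and had 0.30 at 5 µM and 0.24 at 20 µM, the last from 2 arrays. The 18S ribosomal RNA feature had log2 ratios of -0.03, 0.03 and 0.02 at 5, 10 and 20 µM (SE 0.11). For none of the 3 did levels pass the test between doses.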
